A study of Drosophila melanogaster with 35 samples.

How the data were processed

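The series holds 35 2-colour cDNA arrays of Drosophila Kc167 cells. Per the labels, a full-length coding sequence was cloned behind Dam with a Myc tag and the plasmid was transfected, cells with the Dam plasmid alone served for the other channel, and genomic DNA was hybridised with the dyes swapped on part of the arrays. As deposited by the authors, the values are log ratios of Dam-fusion over Dam, taken here as log2. The base is not given in the sources used here. Base 10 was excluded by the range of the values, while base e was not, so printed sizes depend on that reading and the tests do not. Arrays with opposite dyes correlated above 0, so the deposited ratios ran in the same direction on both. High ratios at the own genes of HP1, HP3, HP4, HP5 and Jra place the fusion in the numerator. For the array labelled HP3 replicate 2, which correlates with no other, this could not be checked. The medians of the 35 deposited columns lay between -0.00017 and 0.00027, so the authors had centred them. The scanner, the background correction, the normalisation and the genome build are not given in the sources used here. Scanned images and intensities were not analysed here, so signal over background is unknown.

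The table has 9993 probes, with 434 values missing, which is 0.12% of all. Probes were named through the gene names supplied with the array and a RefSeq gene table for the Release 6 assembly, which was used only for current symbols, chromosomes and the order of genes. Of the probes, 8682 have 1 gene, 298 have several and 1013 are unnamed here. The named probes stand for 7736 genes, of which 858 have more than 1 probe. Probes of a gene were averaged for the tests of gene lists and kept apart elsewhere.

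Arrays were grouped by the labels alone, into 11 groups, and each array was centred on its median. A limma model with 1 mean per group and a dye term was fitted to all 35 arrays, with 23 residual degrees of freedom and a prior of 6.91. A probe needed values on at least 2 arrays of each group, which kept 9934 probes and left out 59. The dye term passed for 65 probes. Tests were two-sided, with p-values adjusted by the method of Benjamini and Hochberg within each comparison and a threshold of 0.05. The comparisons were each of the 7 proteins against 0, the mean of the 6 heterochromatin proteins against Jra, HP1 against white knock-down for HP3 and for HP6, and the difference between those knock-down effects. Counts of chance overlap multiply the shares of probes in each list. Values after ± are SD between arrays unless SE is written, and the SE is that of the model.

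Gene lists were tested with camera in limma at a preset correlation of 0.01, and again with the correlation estimated from the residuals, and adjusted over the lists of each comparison. The lists were every gene of chromosome 4, a hand list of chromosome 4 genes, the 100 genes nearest the centromere and the 20 nearest the telomere of each of 5 arms, a hand list of pericentric genes, region 31 of arm 2L from bsk to da, genes of heterochromatin factors, AP-1 and JNK pathway genes, Polycomb targets and ribosomal protein genes. A list needed 5 genes on the array. Transposable elements (0 on the array) and histones (3) were therefore not tested, and the genes of the fusion proteins (5) were reported singly. For each knock-down, the mean over HP1-bound or Jra-bound probes minus that of all other probes was compared between arrays by exact permutation, and the set was compared with all other probes by camera. With 3 against 3 arrays the smallest two-sided permutation p is 0.1, and with 2 against 2 it is 0.333.

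Genes named in the text follow a rule. For each protein they are the 10 with the highest mean among probes that passed, had a single symbol and lay above 0 on every array of that protein. For the contrast with Jra they are the 10 highest and 10 lowest that passed. Each knock-down contrast names the 12 most fallen and 12 most risen that passed with arrays that do not overlap, or, with fewer than 5, the 5 with the lowest p each way. For the lists up to 3 members with the largest mean are named, and the genes of the fusion proteins are given where they were measured.

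The groups, the model, the tests, the named-gene rule and most alternatives were chosen before the data were examined. Those alternatives were no dye term, no centring, scaling each array to the same median absolute deviation, only the arrays compared, only the 9697 probes with a value on every array, the replicate number as a block, each array left out in turn, the estimated correlation for gene lists, each probe on its own in the lists, and other probe sets, Spearman correlation or opposite-dye pairs. Chosen after the data were seen were the fit without 2 doubted arrays, the estimated correlation for the 2 shifts, the lists without the genes of the fusion proteins, and the split of HP1-bound probes by Su(var)3-9.

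The whole procedure was tested on simulated data with 200 of 9934 probes changed. For HP1 it recovered 17.6%, 84.8% and 100% of changes of 0.5, 1 and 2 in log2, for the HP3 knock-down 1.49%, 41.1% and 91.7%, and for the HP6 knock-down 0%, 14.8% and 77.8%. For the gene lists, the genes of chromosome 4 were moved by -0.5 in the HP3 arrays after HP1 knock-down. This touched 4 tests, of that list and of the hand list within it in 2 contrasts. All 4 were called, and 2 of the 166 other tests. The simulated noise was independent between probes, so this does not measure false calls among lists whose genes vary together. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.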

Results

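DamID profiles of 7 Drosophila proteins were analysed in Kc167, a cell line derived from embryos. In DamID a protein is fused to the bacterial DNA adenine methyltransferase Dam, DNA near its binding sites becomes methylated, and the methylated fragments are compared on a 2-colour array with those from cells that express Dam alone. The 35 arrays fall into 11 groups. Untreated cells were profiled for HP1 (4 arrays), Su(var)3-9 (3), HP3 (4), HP4 (4), HP5 (4) and HP6 (3), and for the transcription factor Jra (3) as a protein outside heterochromatin. HP3 was also profiled after knock-down of HP1 (3 arrays) or of the control gene white (3), and HP6 after the same knock-downs (2 and 2). Each value is the log ratio of fusion over Dam at a cDNA probe, read here as log2 because the base of the logarithm is not given in the sources used here. The number of arrays per group limits the precision. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. A probe is called bound where the mean ratio of a protein lay above 0 with a limma adjusted p under 0.05 (two-sided), out of 9934 probes tested.

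Probes for the genes of the fusion proteins served to check the labels. Because each coding sequence was carried into the cells on a plasmid, a high ratio at its own probe identifies the fusion and is no evidence of binding there, although counts of probes past the threshold include it. The probe for the gene of HP1 averaged 3.53 ± 0.77 (SD, n = 4) on the HP1 arrays and reached at most 1.63 on the 31 others. For HP5 and Jra the own probe averaged 4.02 ± 0.94 (SD, n = 4) and 4.66 ± 0.19 (SD, n = 3), against highest values of 2.18 and 0.20 elsewhere. The Lhr probe, for the gene of HP3, lay between 3.52 and 6.19 on 9 of the 10 HP3 arrays and at 0.09 on the array labelled HP3 replicate 2, against at most 0.24 on the 25 arrays of other fusions. The HP4 probe averaged 4.57 ± 0.58 (SD, n = 4) on the HP4 arrays, and it also read 4.81 on the array labelled HP6 replicate 3, where the next highest of the other arrays had 1.25. Counts for HP3 and HP6 are therefore also given without these 2 arrays, a choice made after the values were seen. The genes of HP6, Su(var)3-9 and white were not analysed here.

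The 6 heterochromatin proteins had similar profiles and Jra had a different one. Across probes, which are not independent replicates, the correlations of the 15 pairs of heterochromatin proteins had a median of 0.71, from 0.583 for Su(var)3-9 with HP3 to 0.871 for HP4 with HP5. The 6 pairs with Jra ranged from -0.298 to -0.0481. Whether Dam-only DNA was shared between arrays is not given in the sources used here, so part of any correlation may come from such sharing. By rank correlation the 15 pairs had a median of 0.623, with HP1 and HP3 lowest at 0.379. Between arrays of opposite dye it was 0.59, again lowest for HP1 with HP3, at 0.442. The median of the 15 pairs was 0.626 without genes of chromosome 4 and the centromere-proximal regions. HP1 shared 556 bound probes with HP6 against 59.3 in independent lists, 286 with HP3 against 36.9, and 470 with Su(var)3-9 against 133, but 45 with Jra against 91.3. All 6 heterochromatin proteins bound 210 probes. Of these, 142 map to a single gene and make 133 genes, 23 on chromosome 4 and 44 among the centromere-proximal genes. Only 8 of the 210 were also bound by Jra, where 22.8 would follow from independent lists. All these overlaps include the 2 doubted arrays, without which 385 of the 700 HP6-bound and 319 of the 435 HP3-bound probes stayed bound. Without the array labelled HP6 replicate 3 and that labelled HP3 replicate 2, the correlation of HP6 changed from 0.815 to 0.667 with HP1 and from 0.727 to 0.503 with Su(var)3-9, and that with Jra from -0.0495 to 0.122.

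**Figure D1:**
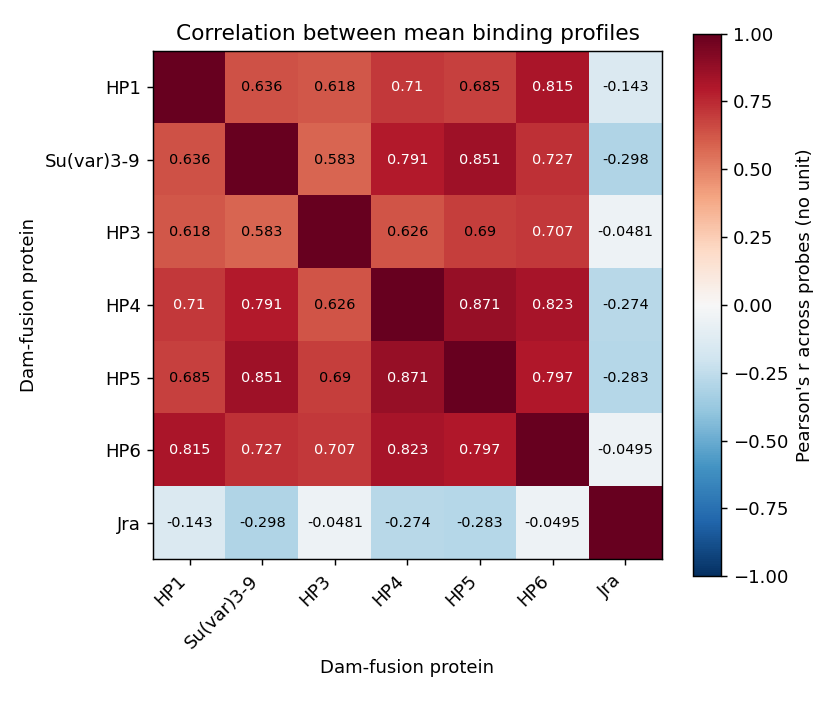
Pearson correlation across probes between the mean log2 ratio profiles of the 7 proteins in untreated cells, as a matrix with the value printed in each cell. The 15 pairs of heterochromatin proteins lie between 0.583 and 0.871, and the 6 pairs with Jra between -0.298 and -0.0481.

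The first question was where each heterochromatin protein binds. HP1 bound genes of the small chromosome 4 and of the regions next to the centromeres most strongly. Its highest named genes were Cht10, a chitinase gene, at 3.95 ± 0.49 (SD, n = 4), CG2519 at 3.58, the catenin gene p120ctn at 3.56, the gene of HP1 itself at 3.53, and hob at 3.51. Next came the ankyrin gene Ank at 3.42, the cadherin gene kug at 3.30, CG17528 at 3.26, the transcription factor gene Atf6 at 3.25 and Gyf at 3.23. Of the 48 measured genes of chromosome 4, 35 were bound (38 when adjusted over the list alone), led by Ank, Gyf and Hcf at 3.42, 3.23 and 3.17 (camera adjusted p = 9.74e-42). Of 28 chromosome 4 genes named by hand, which are part of that list, 22 were bound (23 when adjusted over the list alone). Among 235 centromere-proximal genes 97 were bound (104 when adjusted over the list alone, adjusted p = 7.4e-22), and among 11 known pericentric genes 10 were, including Cht10, p120ctn and Parp1, the gene of a poly(ADP-ribose) polymerase (10 when adjusted over the list alone, adjusted p = 3.19e-22). These 4 calls held with an estimated correlation, with adjusted p of 0.000473, 0.000356, 0.000292 and 0.000559. On the other arms HP1 bound between 5.97% and 9.63% of genes, against 72.9% on chromosome 4.

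Outside these regions, HP1 bound 7 of 31 genes of cytological region 31 on arm 2L, with the ubiquitin ligase gene Ufd4 at 2.97, the demethylase gene Utx at 1.78 and Cand1 at 1.75 (7 when adjusted over the list alone). This list had an adjusted p of 0.00375 by camera and an adjusted p = 0.112 with an estimated correlation. Among 15 genes of heterochromatin factors 3 passed above 0 (4 when adjusted over the list alone), of which the gene of HP1 is the fusion's own and sov at 2.34 and wde at 1.11 were bound (adjusted p = 0.0361, and adjusted p = 0.0455 with an estimated correlation). Without the genes of the fusion proteins that list no longer passed (adjusted p = 0.0571). Of 58 telomere-proximal genes emp at 1.02 and faf at 0.62 were bound, with a list median of -0.03 and a mean of 0.03 (adjusted p = 0.931). Only slpr, at 1.14, was bound among 12 genes of the AP-1 and JNK pathway (adjusted p = 0.931). No member of the list of 11 Polycomb targets was called by limma, the highest being slp2 at 0.10 (adjusted p = 0.726), and RpS19b at 0.83 was the single bound gene among 34 for ribosomal proteins (adjusted p = 0.726). In all, HP1 bound 842 probes, 544 of them with a mean over 1, and 293 probes lay below 0. With each array scaled to the same spread the split was 1020 above and 606 below. Without the 2 doubted arrays it was 885 and 370, with 840 and 289 shared. The number below 0 was 132, 59 and 448 without replicate 1, 2 or 4, and 38 in the fit on the HP1 arrays alone.

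**Figure D2:**
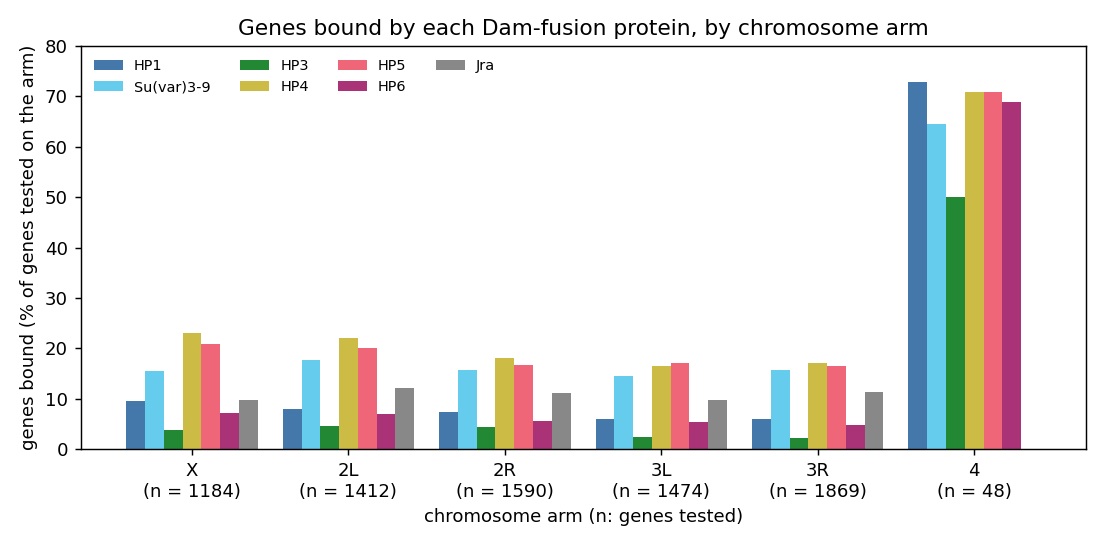
Percent of measured genes bound by each of the 7 proteins on each chromosome arm, with the number of genes tested under each arm. HP1 bound 72.9% of the 48 genes on chromosome 4 and between 5.97% and 9.63% on the other arms, and Jra bound 0% on chromosome 4.

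Su(var)3-9, a histone H3 lysine methyltransferase, led with the same chitinase gene. Cht10 stood at 4.52 on the fitted scale and 4.47 ± 1.47 (SD, n = 3) as a plain mean, followed by CG5532 at 4.42, Parp1 at 3.98 and Fst at 3.67. Then came the potassium channel gene sei at 3.60, Sbf at 3.34, CG8475 at 3.31, kug at 3.30, hob at 3.25 and the ubiquitin protease gene puf at 3.25. The values of Fst and sei rest on replicate 1, without which they were 0.16 (adjusted p = 0.718) and 1.41 (adjusted p = 0.0276). Without replicate 3 Fst stood at 5.61, and in the fit on the Su(var)3-9 arrays alone neither Fst (adjusted p = 0.235) nor sei (adjusted p = 0.0946) passed. Chromosome 4 had 31 of 48 genes bound (33 when adjusted over the list alone), led by Ank at 2.78 and Kif3C at 2.71, with an adjusted p of 5.5e-11 by camera and an adjusted p = 0.138 with an estimated correlation. The hand list had 19 of 28 (22 when adjusted over the list alone, adjusted p = 2.02e-09, and adjusted p = 0.138 with an estimated correlation). Known pericentric genes had 8 of 11 (8 when adjusted over the list alone, adjusted p = 3.85e-06, and adjusted p = 0.138 with an estimated correlation), and 74 of 235 centromere-proximal genes lay above and 41 below 0 (78 and 45 when adjusted over the list alone, adjusted p = 0.0146, and adjusted p = 0.251 with an estimated correlation). That last call was also lost with each array scaled to the same spread (adjusted p = 0.0965).

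Telomere-proximal genes and AP-1 and JNK genes lay below 0 as lists on the Su(var)3-9 arrays at the preset correlation only. Of 58 telomere-proximal genes 23 were below 0 and 4 above, among them the tumour suppressor gene l(2)gl at 1.88 (adjusted p = 0.00456, and adjusted p = 0.164 with an estimated correlation). In the AP-1 and JNK list 4 of 12 were below and 0 above, with puc, Ets21C and Gadd45 lowest (adjusted p = 0.0036, and adjusted p = 0.155 with an estimated correlation). Ribosomal protein genes had 9 of 34 bound, led by RpL10Ab at 1.47 and RpS29 at 1.27 (adjusted p = 0.0375, and adjusted p = 0.251 with an estimated correlation). Region 31 had 6 of 31 bound with Ufd4 at 2.71 (adjusted p = 0.797, median -0.09, mean 0.08), heterochromatin factors 1 of 15, sov at 1.67 (adjusted p = 0.972), and Polycomb targets 2 of 11, salm at 1.18 and vg at 0.50 (adjusted p = 0.797). In all 1569 probes were bound and 1725 lay below 0. Each array counts here, since 813, 995 and 1040 probes were bound without replicate 1, 2 or 3. Without replicate 1 the number below 0 was 971.

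HP3, the product of Lhr, bound genes of chromosome 4 and of the regions next to the centromeres. After Lhr itself at 3.29 ± 2.26 (SD, n = 4), the highest genes were Hcf on chromosome 4 at 2.60 ± 0.47 (SD, n = 4), Cht10 at 2.57, the RNA methyltransferase gene Nsun2 at 2.55, COX4L at 2.51, CG5532 at 2.37, Atf6 at 2.25, CG31249 at 2.25, CG2519 at 2.17 and the acetyltransferase gene Tip60 at 2.10. These means, and the rule that a named gene lies above 0 on every array, include the array labelled HP3 replicate 2. Which genes would be named without it was not examined. The call for CG5532 was lost without replicate 1 (2.03, adjusted p = 0.167), 3 (2.06, adjusted p = 0.123) or 4 (2.27, adjusted p = 0.13). In the fit on the HP3 arrays alone Lhr, Cht10, CG5532, Atf6, CG31249, CG2519 and Tip60 did not pass, with adjusted p between 0.0702 and 0.192. HP3 bound 24 of 48 genes on chromosome 4 (35 when adjusted over the list alone, adjusted p = 4.71e-26), and 15 of the 28 in the hand list (22 when adjusted over the list alone). It also bound 60 of 235 centromere-proximal genes (77 when adjusted over the list alone, adjusted p = 9.89e-13) and 10 of 11 known pericentric genes (11 when adjusted over the list alone, adjusted p = 5.3e-18). With an estimated correlation these calls held, with adjusted p between 0.00382 and 0.00492.

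Of the other groups on HP3 arrays, ribosomal protein genes passed with 4 of 34 bound, among them RpL32 at 0.90 and RpL41 at 0.74 (6 when adjusted over the list alone, adjusted p = 0.000327, and adjusted p = 0.0381 with an estimated correlation). Region 31 had 5 of 31 bound, led by CG31715 at 1.79 (adjusted p = 0.00369, and adjusted p = 0.102 with an estimated correlation), and the telomere-proximal list 5 of 58, led by emp at 1.5 and galectin at 0.97 (adjusted p = 0.0145, and adjusted p = 0.174 with an estimated correlation). Heterochromatin factors had sov bound, at 1.21, and the fusion's own gene Lhr above the threshold (adjusted p = 0.0268, and adjusted p = 0.0381 with an estimated correlation), but the list did not pass without the genes of the fusion proteins (adjusted p = 0.488). Neither the AP-1 and JNK genes (adjusted p = 0.111) nor the Polycomb targets (adjusted p = 0.933) had a member called by limma. In all 435 probes were bound and 229 lay below 0, while 2185 had an unadjusted p under 0.05 by limma. Scaling each array to the same spread gave 1103 above and 951 below, where HP1 had 1020 above and HP6 953, so the order of these proteins by count depends on the scaling. The fit on the HP3 arrays alone called 21 above and 0 below. Without replicate 1 the counts were 281 and 75, and without replicate 4 they were 257 and 41. Without the 2 doubted arrays 487 were bound, of which 319 were shared, and 417 lay below 0.

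HP4 bound genes of chromosome 4 and of the regions next to the centromeres. Its own gene HP4 stood at 4.57 ± 0.58 (SD, n = 4), CG5532 at 4.30, Cht10 at 4.24 ± 0.49 (SD, n = 4), CG2519 at 4.12, and kug at 4.07. Parp1 followed at 3.92, the dynein heavy chain gene Dhc64C at 3.91, p120ctn at 3.88, CG41099 at 3.87 and the mannosidase gene beta-Man at 3.84. On chromosome 4 HP4 bound 34 of 48 genes (36 when adjusted over the list alone, adjusted p = 1.79e-14), and 21 of the 28 in the hand list (22 when adjusted over the list alone). It bound 8 of 11 known pericentric genes (9 when adjusted over the list alone, adjusted p = 4.69e-09). With an estimated correlation these 3 lists had an adjusted p of 0.0497 each. Centromere-proximal genes had 89 above and 36 below 0 (94 and 39 when adjusted over the list alone, adjusted p = 7.98e-06, and adjusted p = 0.0516 with an estimated correlation). Telomere-proximal genes had 20 below and 5 above (adjusted p = 0.0107, and adjusted p = 0.197 with an estimated correlation), and AP-1 and JNK genes 7 of 12 below, puc and Gadd45 lowest, with slpr above at 1.02 (adjusted p = 0.00907, and adjusted p = 0.188 with an estimated correlation). Ribosomal protein genes with 7 above and 2 below (adjusted p = 0.0818), heterochromatin factors with 3 and 3 (adjusted p = 0.997, median -0.20, mean 0.27), region 31 with 5 and 9 (adjusted p = 0.997, median -0.08, mean 0.08) and Polycomb targets with 0 and 1 (adjusted p = 0.908) did not pass as lists. In all 1958 probes were bound and 2165 lay below 0, against 387 and 220 in the fit on the HP4 arrays alone. HP4 replicate 2, which is not among the doubted arrays, correlated with the other HP4 arrays at only 0.401 to 0.423. Its median absolute deviation of 1.088 was the largest of all arrays. Without HP4 replicate 2 the number bound was 1471. Scaling each array to the same spread gave 1292 and 1565.

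HP5 led with Parp1 at 4.27 ± 0.30 (SD, n = 4) and its own gene HP5 at 4.02 ± 0.94 (SD, n = 4). Cht10 followed at 3.54, the chromosome 4 gene toy, a Pax6 homologue, at 3.40, Atf6 at 3.39, p120ctn at 3.30, CG2519 at 3.29, CG10993 at 3.19, CG31249 at 3.12 and kug at 3.06. It bound 34 of 48 genes on chromosome 4 (35 when adjusted over the list alone, adjusted p = 7.38e-14), and 19 of 28 in the hand list (19 when adjusted over the list alone). Bound too were 92 of 235 centromere-proximal genes with 37 below 0 (95 and 39 when adjusted over the list alone, adjusted p = 6.71e-06) and 8 of 11 known pericentric genes (9 when adjusted over the list alone, adjusted p = 4.69e-09). Each of these 4 lists had adjusted p = 0.0549 with an estimated correlation. Ribosomal protein genes had 10 of 34 bound, including RpL10Ab at 1.17 and RpLP0 at 0.79 (adjusted p = 0.00432, and adjusted p = 0.119 with an estimated correlation). Telomere-proximal genes had 18 below and 5 above (adjusted p = 0.0201, and adjusted p = 0.224 with an estimated correlation), and AP-1 and JNK genes 5 below and 0 above (adjusted p = 0.00859, and adjusted p = 0.164 with an estimated correlation). Region 31 with 8 above and 5 below (adjusted p = 0.807, median -0.13, mean 0.05), heterochromatin factors with 3 and 4 (adjusted p = 0.807, median -0.03, mean 0.30) and Polycomb targets with none called by limma (adjusted p = 0.807) did not pass as lists. In all 1823 probes were bound and 1857 lay below 0, against 1151 and 1067 without replicate 1.

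HP6 bound hob most strongly, at 3.28 on the fitted scale and 3.22 ± 1.11 (SD, n = 3) as a plain mean. The means of the genes named here include the array labelled HP6 replicate 3. The kinase gene gek followed at 3.21, Cht10 at 3.11, the acetyltransferase gene enok at 3.09, conu at 3.09, kug at 3.04, p120ctn at 3.04, toy at 3.02, puf at 3.01 and Dhc64C at 2.97. It bound 33 of 48 genes on chromosome 4 (35 when adjusted over the list alone, adjusted p = 7.16e-30), and 21 of 28 in the hand list (21 when adjusted over the list alone). It also bound 75 of 235 centromere-proximal genes (87 when adjusted over the list alone, adjusted p = 4.45e-13) and 10 of 11 known pericentric genes (10 when adjusted over the list alone, adjusted p = 1.75e-16). Each of these lists had adjusted p = 0.00276 with an estimated correlation. Region 31 had 6 of 31 bound (adjusted p = 0.0186, and adjusted p = 0.243 with an estimated correlation) and ribosomal protein genes 3 of 34 (adjusted p = 0.0334, and adjusted p = 0.243 with an estimated correlation). Among heterochromatin factors sov at 2.31 and HP4 at 1.71 passed (adjusted p = 0.862, median -0.07, mean 0.18), and the HP4 value includes the 4.81 of the array labelled HP6 replicate 3. Telomere-proximal genes (3 bound, adjusted p = 0.531), AP-1 and JNK genes (adjusted p = 0.767) and Polycomb targets (adjusted p = 0.531) did not pass, the last 2 lists with no member called by limma. Relative to other genes, the telomere-proximal list stood at 0.251 and 0.158 on replicates 1 and 2. On the array labelled HP6 replicate 3 it stood at -0.298, so the HP6 mean joins values of opposite sign. Of 700 bound probes, with 331 below 0, 385 were shared with the 475 bound without the 2 doubted arrays, which left 119 below 0. Without replicate 3 alone 432 were bound and 95 lay below 0, and in the fit on the HP6 arrays alone 462 and 98. Without replicate 2 the number below 0 was 101, and with each array scaled to the same spread it was 666.

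Jra, the Drosophila homologue of the AP-1 subunit Jun, bound other genes. After its own gene at 4.68 came the dynein light chain gene ctp at 2.25, measured on only 2 of the arrays with an SD of 2.76 and not past the threshold in the fit on the Jra arrays alone (adjusted p = 0.0745), and the circadian repressor gene cwo at 2.15. The others were spict at 2.08, stck at 1.92, CG15012 at 1.88, the prefoldin gene Pfdn2 at 1.87, the serpin gene Spn55B at 1.86, Vta1 at 1.84 and GATAd at 1.84. Among AP-1 and JNK genes 5 of 12 passed above 0, of which Jra is the fusion's own, with puc, the phosphatase gene of the JNK pathway, at 1.62 and Ets21C at 0.95 (5 when adjusted over the list alone). That list had an adjusted p of 0.0069 by camera and an adjusted p = 0.479 with an estimated correlation, and without Jra itself it did not pass (adjusted p = 0.179). Jra bound 0 of 48 genes on chromosome 4 and 0 of 11 known pericentric genes by limma, with 4 and 1 below 0, and 12 of 235 centromere-proximal genes with 17 below 0 (adjusted p = 0.432, 0.679 and 0.841). On the other arms it bound between 9.71% and 12.1% of genes. Telomere-proximal genes with 7 bound, led by Nhe1 at 1.31 (adjusted p = 0.179), ribosomal protein genes with 4 bound, led by RpS20 at 1.06 (adjusted p = 0.179), and region 31 with 4 bound (adjusted p = 0.302) did not pass as lists. None of the heterochromatin factors or Polycomb targets was called by limma (adjusted p = 0.841 each), nor any of the 28 chromosome 4 genes of the hand list as bound (adjusted p = 0.589, median 0.01, mean -0.09). In all 1077 probes were bound and 626 lay below 0. Without replicate 1 the counts fell to 590 and fewer than 210, and without replicate 2 to 517 and 161.

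The 6 heterochromatin proteins were then compared with Jra directly. The mean of the 6 exceeded Jra most at Parp1, by 4.42 ± 0.41 (SE), with 3.32 as the mean of the 6 protein means and -1.13 ± 0.21 (SD, n = 3) for Jra. Cht10 at 4.34, CG5532 at 4.33, p120ctn at 4.10, CG2519 at 3.96, kug at 3.93, hob at 3.71, the helicase gene mus301 at 3.63, CG41099 at 3.61 and the cohesin loader gene Nipped-B at 3.61 followed. Jra exceeded the mean of the 6 at its own gene, with a difference of -5.00, and at cwo (-3.07), spict (-2.86), the amino acid transporter gene mnd (-2.68), CG32756 (-2.63), stck (-2.61), Pfdn2 (-2.56), Nmda1 (-2.54), puc (-2.46) and nes (-2.42). The adjusted p of these 20 genes lay between 4.45e-11 and 0.000142.

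By gene group, 36 of 48 chromosome 4 genes were higher for the heterochromatin proteins and 0 lower (38 and 0 when adjusted over the list alone, adjusted p = 4.31e-14), as were 23 of 28 in the hand list (24 when adjusted over the list alone). So were 81 centromere-proximal genes against 28 lower (87 and 30 when adjusted over the list alone, adjusted p = 3.06e-05) and 8 of 11 known pericentric genes (8 when adjusted over the list alone, adjusted p = 3.17e-07). Each of these lists had adjusted p = 0.0663 with an estimated correlation. AP-1 and JNK genes were lower, 6 of 12 with slpr higher at 0.96 (adjusted p = 0.000467, and adjusted p = 0.0663 with an estimated correlation), and the call held without the genes of the fusion proteins (adjusted p = 0.00699). Telomere-proximal genes were lower, 17 against 3 (adjusted p = 0.038, and adjusted p = 0.314 with an estimated correlation), a call that was lost with each array scaled to the same spread (adjusted p = 0.0805) or without the 2 doubted arrays (adjusted p = 0.0626). Region 31 (7 higher, 6 lower), ribosomal protein genes (5 and 3) and Polycomb targets (1 and 0) had an adjusted p of 0.995 each, and heterochromatin factors (1 and 2) one of 0.543. The first 3 of these had a median and a mean of opposite sign. In all 1683 probes were higher and 1900 lower. Without Jra replicate 1 or 2 the higher count was 900 or 890.

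**Figure D3:**
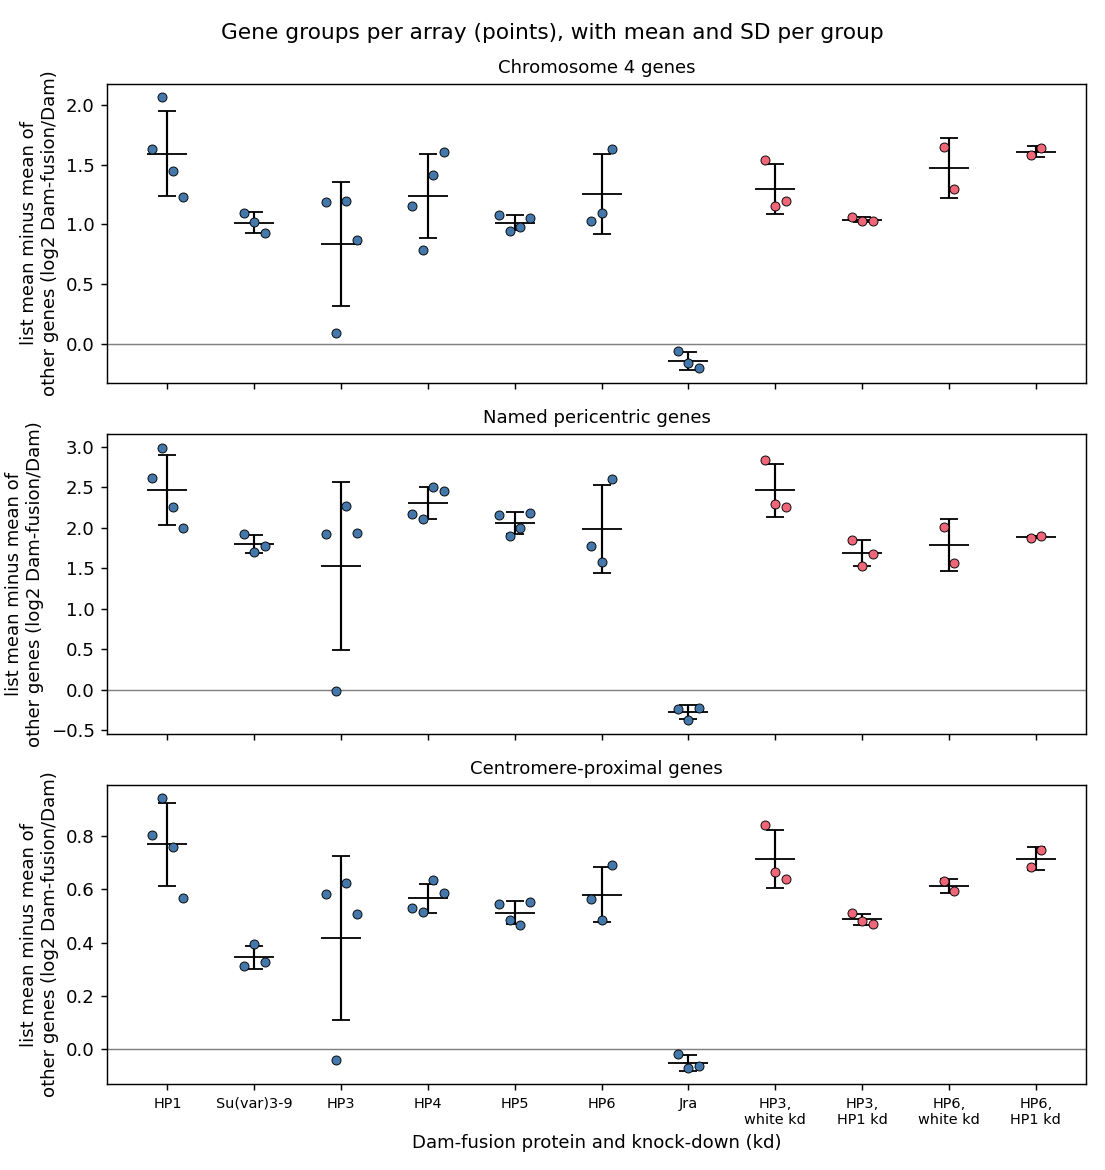
Mean log2 ratio of genes of chromosome 4, known pericentric genes and centromere-proximal genes, each minus the mean of all other genes, 1 point per array. The 7 proteins in untreated cells and the HP3 and HP6 knock-down groups are shown, with the group mean and SD. The 3 Jra arrays lie below 0 for genes of chromosome 4, at -0.14 ± 0.07, where HP1 had 1.59 ± 0.35, and the array labelled HP3 replicate 2 lies near 0 for the known pericentric genes.

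The next question was whether HP3 and HP6 need HP1 for their positions. After HP1 knock-down HP3 fell past the threshold at 44 probes, most of them bound by heterochromatin proteins, and rose at 738. These counts depend on the fit, since 706 fell and 1693 rose in the fit on the arrays compared alone. In simulated data 41.1% of changes of 1 in log2 were recovered for this comparison, so falls may be missed. The mean over all 842 HP1-bound probes relative to other probes shifted by -0.496. CG2519 fell from 2.68 ± 0.05 (SD, n = 3) in the white control to 0.83 ± 0.43 (SD, n = 3), a difference of -1.85 ± 0.52 (SE, adjusted p = 0.0212). Marf1 fell from 2.24 ± 0.32 (SD, n = 3) to 0.49 ± 0.18 (SD, n = 3), a difference of -1.75 (adjusted p = 0.00231). CG43367 (-1.73), Dhc64C (-1.73), the eye gene eya (-1.71), the nucleoporin gene Elys (-1.68), Ice1 (-1.65), side-III (-1.62), gek (-1.61), Rcd7 (-1.60), the ATM kinase gene tefu (-1.59) and CG9795 (-1.54) also fell. CG7506 rose most, by 2.54 ± 0.32 (SE), from -0.20 ± 0.18 (SD, n = 3) to 2.34 ± 0.61 (SD, n = 3), with an adjusted p of 9.6e-06. Scox rose by 2.44, Nnk by 2.44, CG32576 by 2.40, CG31441 by 2.30 and CG8237 by 2.27. The elongation factor gene eEFSec rose by 2.21, the small Maf gene maf-S by 2.19, Iru by 2.15, the splicing factor gene Prp38 by 2.15, CG6153 by 2.11 and the mitochondrial ribosomal protein gene mRpS11 by 2.10.

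In all 44 probes fell and 738 rose after HP1 knock-down on the HP3 arrays. Of the 44 that fell 36 were bound by HP1 in untreated cells, against 3.73 in independent lists, and 35 by HP6, against 3.10. Likewise 37 were bound by HP5, 36 by Su(var)3-9, 35 by HP4 and 20 by HP3, against 8.07, 6.95, 8.67 and 1.93, but 2 by Jra, against 4.77. A large fall needs a high control ratio, and the control arrays followed the HP1 profile. The excess over independent lists is therefore not particular to HP1. Of the 738 that rose 11 were bound by HP1, against 62.6, and 168 by Jra, against 80. The 3 arrays of each knock-down did not overlap for 777 of the 782 changed probes and for 42.0% of all probes, where chance gives 10%. Over all 842 HP1-bound probes, the HP3 mean above other probes was 0.54 ± 0.04 (SD, n = 3) after HP1 knock-down and 1.03 ± 0.13 (SD, n = 3) in the control. That shift of -0.50 gave an exact two-sided permutation p of 0.1, the smallest that 3 against 3 arrays allow, with a camera p = 2.42e-13, and p = 0.113 with an estimated correlation. At the 1077 Jra-bound probes the mean moved from -0.10 ± 0.03 (SD, n = 3) to 0.23 ± 0.13 (SD, n = 3). The shift of 0.32 there had an exact permutation p = 0.1, a camera p = 2.94e-10, and p = 0.0749 with an estimated correlation. The correlation of the HP3 arrays with the HP1 profile was 0.681 ± 0.0165 (SD, n = 3) in the control. After HP1 knock-down it was 0.296 ± 0.0829 (SD, n = 3). With the Jra profile these were -0.0532 ± 0.0519 (SD, n = 3) and 0.240 ± 0.0718 (SD, n = 3). The drop was not particular to HP1. With Su(var)3-9, HP4 and HP5 the mean correlations were 0.604, 0.616 and 0.639 in the control and 0.133, 0.166 and 0.157 after HP1 knock-down. With HP3 and HP6 they were 0.758 and 0.64, and 0.444 and 0.401. The profiles left out the 2 doubted arrays.

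Among the gene groups, known pericentric genes were lower, with a mean of 1.69 ± 0.16 (SD, n = 3) against 2.46 ± 0.33 (SD, n = 3) in the control, although only 1 of 11 was called (adjusted p = 0.018, and adjusted p = 0.46 with an estimated correlation). Centromere-proximal genes went both ways, 8 lower and 14 higher, with a list mean of -0.14 (adjusted p = 0.034, and adjusted p = 0.46 with an estimated correlation). Region 31 had 7 higher, including the JNK gene bsk at 1.45 and CG4953 at 1.37, and 1 lower (adjusted p = 0.0295, and adjusted p = 0.46 with an estimated correlation). Chromosome 4 had 4 genes higher, among them Ekar at 1.2 and Gat at 1.16, and 1 lower (adjusted p = 0.104), and its hand list 2 and 0 (adjusted p = 0.137). Telomere-proximal genes (7 higher, led by Gk1 at 1.96, adjusted p = 0.104), ribosomal protein genes (2 higher, RpS20 at 1.40 among them, adjusted p = 0.604), AP-1 and JNK genes (bsk alone, adjusted p = 0.367), heterochromatin factors (HP1b alone, at 0.98, adjusted p = 0.923, median -0.04, mean 0.06) and Polycomb targets (none called by limma, adjusted p = 0.107) did not pass as lists. List members were counted after averaging the probes of each gene, so a probe named above may pass where its gene is not called. The probe for the HP1 gene read -0.54 ± 0.17 (SD, n = 3) after HP1 knock-down and 0.36 ± 0.08 (SD, n = 3) in the control (difference -0.91, adjusted p = 0.286), and that difference passed with each array scaled to the same spread (adjusted p = 0.0298) and in the fit on these arrays alone (adjusted p = 0.00266). DamID gives methylation at that gene and not the level of HP1, so the knock-down itself was not measured.

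The HP3 counts depended on single arrays. Without HP1 knock-down replicate 2 only 3 probes fell and 180 rose, and 10 of the 12 named genes that fell lost their call, with adjusted p between 0.0851 and 0.198 and differences that stayed between -1.81 and -1.32, while Marf1 and gek kept theirs whichever array was left out. Counting that array, calls ended without any 1 of all 6 arrays for Ice1, of 5 for CG43367, of 4 each for CG2519, eya, Elys and side-III, of 3 for Dhc64C and of 2 for tefu. With each array scaled to the same spread CG2519 (adjusted p = 0.106) and CG9795 (adjusted p = 0.0576) did not pass, and side-III did not in the fit on these arrays alone (adjusted p = 0.119). The number that fell was 20 without HP1 knock-down replicate 1, 8 without white knock-down replicate 1, 27 without white replicate 2 and 26 without white replicate 3, and the number that rose was 371 and 438 without white replicates 2 and 3. The value of side-III was -0.61 without white replicate 1 (adjusted p = 0.457). Without the 2 doubted arrays, which lie in other groups, 99 probes fell and 866 rose, including all 44 and 737 of the 738, the fit on these 6 arrays alone called 706 and 1693, and with each array scaled to the same spread 92 fell and 895 rose.

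**Figure D4:**
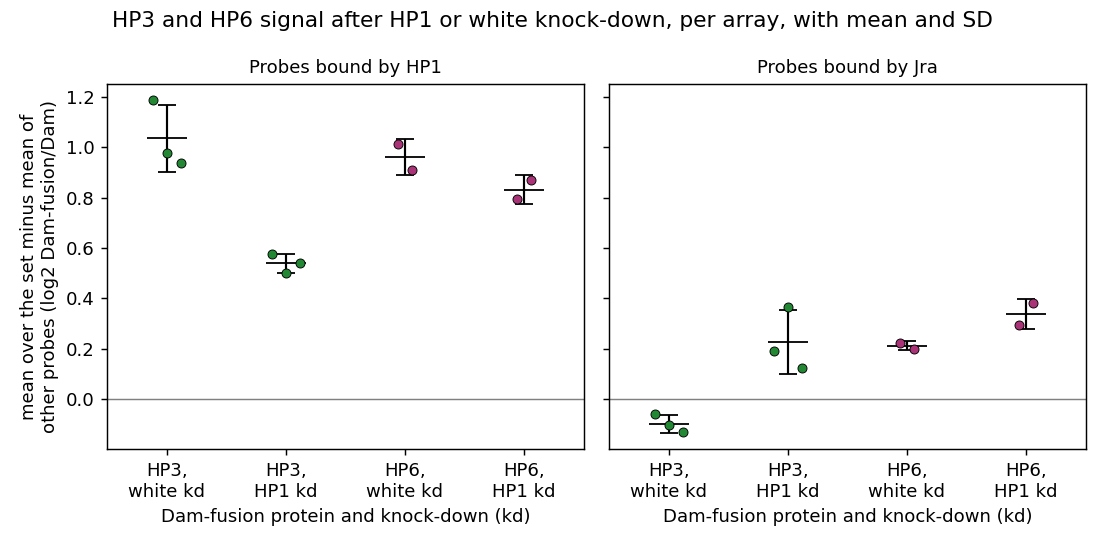
Mean log2 ratio of HP1-bound and of Jra-bound probes minus the mean of all other probes, 1 point per array, for HP3 and HP6 after knock-down of white or HP1. For HP3 the HP1-bound mean was 1.03 ± 0.13 in the white control and 0.54 ± 0.04 after HP1 knock-down, and for HP6 it was 0.96 ± 0.07 and 0.83 ± 0.06.

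For HP6, 2 probes passed after HP1 knock-down, both lower. CG1910 stood at -1.93 ± 2.04 (SD, n = 2) against 0.80 ± 0.77 (SD, n = 2) in the control, a difference of -2.72 ± 0.50 (SE, adjusted p = 0.037). The CBP acetyltransferase gene nej stood at -1.03 ± 0.74 (SD, n = 2) against 0.91 ± 0.70 (SD, n = 2), a difference of -1.94 (adjusted p = 0.037). The other genes with the lowest p did not pass, namely mira (-2.66), CG2186 (-2.65), COX6CL (-2.10), Tbcc (1.37), the homeotic gene Antp (3.67), the clathrin light chain gene Clc (4.66), FoxK (2.47) and Dr (2.93), with adjusted p from 0.233 to 0.828. The SD within the control pair was 6.56 for Clc and 4.78 for Antp. With the replicate number as a block mira and Tbcc passed by limma (adjusted p = 0.0432 each), but the labels do not say that numbers pair the arrays. Tbcc passed with each array scaled to the same spread (adjusted p = 0.0188) and without white replicate 1 (adjusted p = 0.023). CG2186 and COX6CL passed without HP1 knock-down replicate 2 (-4.41 and -3.63), and mira, CG2186, Antp, Clc, FoxK and Dr without white replicate 2 (-4.74, -3.29, 7.07, 9.42, 3.60 and 5.74). Over HP1-bound probes the HP6 mean was 0.83 ± 0.06 (SD, n = 2) against 0.96 ± 0.07 (SD, n = 2). This shift of -0.13 had an exact two-sided permutation p of 0.333, the smallest that 2 against 2 arrays allow, a camera p = 0.00161, and p = 0.486 with an estimated correlation. Without white replicate 1 it was -0.08 and not called (exact permutation p = 0.667, camera p = 0.681). It was -0.22 with each array scaled to the same spread, -0.20 at the 500 probes with the highest HP1 mean and -0.20 at HP6-bound probes. The Jra-bound mean was higher by 0.13, with an exact permutation p = 0.333, a camera p = 3.4e-05, and p = 0.232 with an estimated correlation.

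No gene list had a member called by limma for HP6, where 173 of the 9934 probes had an unadjusted p under 0.05. Region 31 was higher as a list, at a mean of 0.30 with Frmd5 at 0.85 (adjusted p = 0.00016, and adjusted p = 0.138 with an estimated correlation), and so were the centromere-proximal genes, at 0.10 (adjusted p = 0.0213, and adjusted p = 0.705 with an estimated correlation). Chromosome 4 (adjusted p = 0.0704), its hand list (0.398), telomere-proximal genes (0.521), known pericentric genes, heterochromatin factors, AP-1 and JNK genes and Polycomb targets (0.566 each) and ribosomal protein genes (0.762) did not pass. Adjusted over the list alone, 1 Polycomb target was higher. That same HP1 gene probe read -0.81 ± 0.07 (SD, n = 2) against -0.01 ± 0.02 (SD, n = 2) in the control, which did not pass (difference -0.79, adjusted p = 1). CG1910 moved to -1.17 without HP1 knock-down replicate 1 (adjusted p = 1), to -4.27 without replicate 2 (adjusted p = 1.19e-07), and to -2.15 without white replicate 1 (adjusted p = 0.57). The call for nej was lost without HP1 knock-down replicate 2 (adjusted p = 0.914) or white replicate 1 (adjusted p = 0.581). In the fit on these 4 arrays alone CG1910 did not pass (adjusted p = 0.216). Without the 2 doubted arrays both had an adjusted p of 0.0543, so that no probe passed. The count was 7 without HP1 knock-down replicate 2, 7 without white replicate 1 and 31 without white replicate 2. With each array scaled to the same spread it was 5, of which 2 were higher, and in the fit on these 4 arrays alone it was 4.

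The knock-down effects on HP3 and HP6 were compared with each other by a test of the difference. It called 0 probes by limma, with 499 at an unadjusted p under 0.05, and no member of any gene list. Across probes the 2 effects had a correlation of 0.450. Dam-only DNA shared within a knock-down, which the labels leave open, would by itself give a correlation above 0 and a majority of equal signs, so neither is read here as a shared effect. Of the 44 probes that fell for HP3, 40 had an HP6 difference below 0, with a median of -0.67, and of the 738 that rose 655 had one above 0, with a median of 0.27, where 52.1% of all probes were above 0. The count of the difference was 20 without HP6 white knock-down replicate 2, 3 without HP6 HP1 knock-down replicate 2, 2 without HP6 HP1 knock-down replicate 1, 2 without HP3 white knock-down replicate 2 and 1 without HP3 HP1 knock-down replicate 3. It was 4, with 3 higher and 1 lower, with each array scaled to the same spread, 155 in the fit on these 10 arrays alone and 1 without the 2 doubted arrays.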

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

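The tests of DNA from HP4-Dam cells and of a shared batch or reference for the array labelled HP6 replicate 3 were chosen only after the result was seen. The list of known pericentric genes stood at -0.0122 on the array labelled HP3 replicate 2, which a test for a single distant array singled out. It was the only such array among 48 groups of values, where about 1 in 20 groups, or 2.4, would be singled out by chance.

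That array correlated with no other, the highest absolute correlation being 0.0869, and its Lhr probe read 0.0925 where the other untreated HP3 arrays had 3.522 to 5.344. A different sample with its own signal at the right probes is excluded by the correlation between 2 probes of the same gene. It was 0.0281 here and 0.244 to 0.695 on every other array. That correlation does not exclude a sample without signal, or another sample with values at the wrong probes. Symmetric noise is excluded by a skewness of 1.335, within the 0.8672 to 3.041 of the HP3 arrays. Values attached to the wrong probes remain possible, since the median absolute deviation of 0.3715 lay within the HP3 range of 0.2341 to 0.504. Shifting the table by any of 9992 steps gave no absolute correlation above 0.077, and noise with a skewed distribution was not excluded.

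The array labelled HP6 replicate 3 correlated with the HP4 arrays at 0.449 to 0.912. With the other HP6 arrays it correlated at 0.482 and 0.59, and those correlated with each other at 0.599. It correlated nearly as highly with HP5 replicate 4 as with its closest HP4 array. It correlated more highly with Su(var)3-9 replicates 2 and 3 and with HP1 replicate 2 than with HP4 replicates 1 and 2. However, HP4 replicate 1 correlated at 0.716 with this array and at 0.417 to 0.679 with the other HP4 arrays. For HP4 replicate 2 these were 0.449 and 0.401 to 0.423. The lower correlations with HP4 replicates 1 and 2 therefore do not set this array apart from the HP4 arrays. Given HP5 replicate 4, a high correlation is not particular to HP4 either. At the HP4 probe the ratio of 4.806 on the array labelled HP6 replicate 3 lay inside the 3.713 to 5.011 of the HP4 arrays, as DNA from HP4-Dam cells would give. HP5 arrays that correlate with an HP4 array up to 0.893 read at most 0.6819 at that probe. A profile like that of HP4 therefore does not by itself bring a high ratio there. No label names batches or shared Dam-only DNA, so neither could be excluded as a source of the correlation. An equal mixture of HP6 and HP4 DNA is excluded by 28 probes specific to HP6, with a median of -0.438 on this array, 1.01 on the other two HP6 arrays and -0.616 on the HP4 arrays, while a small share of HP6 DNA may be present.

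After HP1 knock-down HP3 was higher at Jra-bound probes, whose mean minus that of probes bound by neither protein was 0.22, 0.388 and 0.15 on the 3 HP1 knock-down arrays and 0.00209, -0.0506 and -0.081 in the control. A wider range of values is excluded by a rise of 0.322 with every array scaled alike, and a single array by 0.255 as the lowest rise with 1 array left out. Centring after loss at HP1-bound probes is excluded by a rise of 0.296 relative to probes bound by neither. On the HP6 arrays the rise relative to probes bound by neither was 0.115. An effect of the loss of HP1 on HP3 and a batch that coincides with the knock-down were not tested apart. Dam-only DNA shared within a knock-down, which the labels leave open, was not tested either. All of these stay open.

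The knock-down effect differed between HP3 and HP6 in the tests of that difference at a preset correlation. The shift at HP1-bound probes differed by -0.367 and that at Jra-bound probes by 0.199, and neither passed with an estimated correlation, where the exact permutation tests were made per protein only and the camera p was 0.177 and 0.204. By list, the difference was -0.315 for all genes of chromosome 4 (adjusted p = 0.000678, and adjusted p = 0.581 with an estimated correlation), -0.253 for the hand list of that chromosome (adjusted p = 0.0159, and adjusted p = 0.597 with an estimated correlation) and -0.247 for centromere-proximal genes (adjusted p = 1.99e-05, and adjusted p = 0.092 with an estimated correlation). It was -0.795 for known pericentric genes (adjusted p = 0.000342, and adjusted p = 0.301 with an estimated correlation) and -0.343 for Polycomb targets (adjusted p = 0.0159, and adjusted p = 0.092 with an estimated correlation), the last with an adjusted p of 0.0603 with each probe on its own.

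The 782 probes changed for HP3 were compared with the other splits of the same 6 arrays. The real split was 1 of 10, and the highest other called 0, but 10 splits are too few for a share under 0.05. For the contrast with Jra, a fit with only 2 groups called 2491 probes, 1 of 100 splits was as large, and the highest other called 818. No other split drawn kept 3 arrays of 1 protein together, and replicates resemble each other, so these splits do not settle whether chance can be excluded.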

How the results depend on the processing

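Leaving out the 2 doubted arrays, the estimated correlation for the shifts, the lists without the genes of the fusion proteins and the Su(var)3-9 split were tests chosen only after the results were seen. Of 3085 values for single genes and lists 2881 kept their direction and their side of the threshold, 149 lost their call, 38 gained one and 17, none of them called, changed sign. Using the values as deposited moved counts by at most 1, because they were already centred, and so tests nothing. Leaving out the dye term or probes with a missing value moved no count by over 1.5 times. For the changes below the cause was not tested, apart from the fewer arrays where an array was left out. A group left with 1 array was assumed to vary like the other groups.

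With each array scaled to the same median absolute deviation, bound probes became 1103 for HP3 and 1292 for HP4, HP3 fell at 92 probes after HP1 knock-down, and 5 probes changed for HP6 (2 higher, 3 lower) and 4 in the difference (3 higher, 1 lower). Signs turned for uncalled values of the HP1 gene (0.0384), HP4 (-0.0364), RpL15 (-0.0999) and cad (0.0878) in the difference, Spf45 (-0.284) in the HP3 knock-down and vg (-0.0311) for HP1. A fit on only the arrays compared bound 21 probes for HP3, 387 for HP4 and 462 for HP6, gave 706 fallen and 1693 risen for HP3, 4 changed for HP6 and 155 in the difference. Without the 2 doubted arrays 99 probes fell for HP3, 0 changed for HP6 and 1 in the difference.

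With an estimated correlation the shift of -0.496 for HP3 and of -0.129 for HP6 no longer passed, and 26 of 170 list tests did, against 89. Each probe on its own gave 90, scaling 86, the lists without the genes of the fusion proteins 84 and the fit without the 2 doubted arrays 88. HP1-bound probes that Su(var)3-9 also bound shifted by -0.759 for HP3 and -0.23 for HP6, those without it by -0.117 and 0.01, and probes bound by Su(var)3-9 without HP1 by -0.28 and -0.183.

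With the replicate number as a block, 4 probes changed for HP6 (1 higher, 3 lower), adding mira and Tbcc (adjusted p = 0.0432 each), HP3 had 674 risen and 42 fallen, the contrast with Jra 1775 higher and 1911 lower, and the difference 0. The labels do not say that numbers pair the arrays. Deviations from the group means correlated at 0.1, 0.073 and 0.24 between arrays of the same number for HP3 and at 0.16 and 0.16 for HP6. With the dye effect removed these were 0.17, 0.21, 0.28, 0.19 and 0.19, and every array correlated best with its own number, a hint from the data and not the design.

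With 1 array left out, bound probes ranged from 663 to 933 for HP1, 813 to 1040 for Su(var)3-9, 257 to 425 for HP3, 1471 to 2000 for HP4, 1151 to 1702 for HP5, 432 to 642 for HP6 and 517 to 852 for Jra. Against Jra 890 to 2018 were higher and 1287 to 2121 lower. For HP3 3 to 35 fell and 180 to 771 rose, for HP6 3 to 31 changed, and in the difference 0 to 20. The shift ranged from -0.543 to -0.42 for HP3 and from -0.18 to -0.0783 for HP6. Signs turned in uncalled values: Clc ranged from -0.0899 to 9.42 for HP6, Lhr from -0.856 to 0.0222 for HP3, from -0.242 to 0.135 for HP6 (also 0.0735) and from -0.802 to 0.076 in the difference, and HP4 from -1.14 to 0.0132 for HP6 and from -0.544 to 0.605 in the difference (also -0.0569, -0.139, -0.164 and -0.465).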

Other observations

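No test in this part was chosen after its result was seen, apart from the split by Su(var)3-9 and the fit without the 2 doubted arrays. HP1-bound probes were divided into 470 that Su(var)3-9 also bound and 372 that it did not. For the 470 the HP3 mean above other probes was 0.57 ± 0.10 (SD, n = 3) after HP1 knock-down and 1.32 ± 0.15 (SD, n = 3) in the control, and for the 372 it was 0.45 ± 0.06 (SD, n = 3) and 0.57 ± 0.10 (SD, n = 3). The exact two-sided permutation p was 0.1 for the 470, with a camera p of 0.0765 with an estimated correlation, and 0.2 for the 372. The difference between the 2 sets, which started from unequal levels, was not tested. For HP6 the shifts were -0.23 and 0.01.

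At the probes for the other fusion genes no knock-down contrast passed in the fit on all 35 arrays, while in the fit on the 6 HP3 arrays compared HP5 (adjusted p = 0.00167) and HP4 (adjusted p = 0.0327) did. On all arrays HP3 differed by -0.51 at Lhr (adjusted p = 0.76), -0.53 at HP4 (adjusted p = 0.765), 1.48 at HP5 (adjusted p = 0.0738) and 0.42 at Jra (adjusted p = 0.708), and HP6 by -0.05, -0.56, 0.32 and 0.56 (adjusted p = 1 each). The difference between the 2 effects was -0.11 at the HP1 gene, -0.46 at Lhr, 0.03 at HP4, 1.15 at HP5 and -0.14 at Jra (adjusted p = 1 each). The contrast of the heterochromatin proteins with Jra includes each fusion's own arrays, where the plasmid gives a high ratio. At the HP4 gene the HP4 arrays averaged 4.57. At the HP1 gene the HP1 arrays averaged 3.53 and the other heterochromatin proteins between -0.657 and 0.794. In that contrast the value was 0.82 at the HP1 gene (adjusted p = 0.0591). That gene passed with each array scaled to the same spread (0.93, adjusted p = 0.00143), without HP4 replicate 2 (0.94, adjusted p = 0.0033), without HP1 replicate 3 (adjusted p = 0.0478) or 4 (adjusted p = 0.0449), and without HP3 replicate 3 (adjusted p = 0.0487). The other values were 0.43 at Lhr (adjusted p = 0.521), 1.05 at HP4 (adjusted p = 0.123, and 0.82 with adjusted p = 0.0478 without the 2 doubted arrays or adjusted p = 0.0461 without HP6 replicate 3 alone) and 0.42 at HP5 (adjusted p = 0.409).

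Replicate arrays correlated at a median of 0.601 for HP1, 0.726 for Su(var)3-9, 0.295 for HP3, 0.54 for HP4, 0.705 for HP5, 0.59 for HP6 and 0.518 for Jra. On the knock-down arrays it was 0.877 and 0.824 for HP3 and 0.771 and 0.675 for HP6, after HP1 and white knock-down respectively.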
